A study of Mus musculus with 4 samples.

How the data were processed

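Liver RNA of male mice from a polygenic obese line was compared after 14 days on either of 2 diets. One held the trans-10, cis-12 isomer of conjugated linoleic acid (CLA) at 1%, and the control diet held linoleic acid at the same level. Per the labels, RNA was pooled from 4 or 5 mice per sample and labelled directly, and each of 4 two-colour Agilent oligonucleotide arrays held 1 CLA sample against 1 control sample. CLA was in the red dye Cy5 on arrays 1 and 2 and in the green dye Cy3 on arrays 3 and 4. The labels do not say which arrays share a pool. Each array therefore entered as 1 sample, and p-values measure only the spread between these arrays, which may be technical. The difference between arrays 2 and 1 and that between arrays 4 and 3 had r = 0.07 across genes. This gives no hint of pools shared between the dye orientations. It cannot show whether arrays 1 and 2, or arrays 3 and 4, shared a pool.

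Per the file headers, the deposited scanner files were made with Agilent Feature Extraction A.6.1.1 and hold, for each of 22393 spots, the mean foreground and median local background intensity in both channels, with flags for outliers, saturation and signal above background. They also hold processed intensities, corrected for background and dye, and the log10 ratio of Cy5 over Cy3 made from them. The deposited series matrix holds a log10 ratio per spot whose making is not given in the sources used here. Set against the scanner's log10 ratio it had a slope of 1 on arrays 1 and 2 and of -1 on arrays 3 and 4, so it runs as CLA over control on every array. Its column medians were 0.0042, 0.00034, -0.0063 and -0.0068. The authors' deposited table of significant liver genes gives a ratio, a p-value and a signed fold change, a score that equals the ratio or minus its inverse, for 775 probes. The test behind that p-value is not given in the sources used here.

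Mean foreground intensities were corrected with normexp (offset 50) against the median local background and normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots (1075 per array) were then removed, spots with an outlier flag were set missing, and spots of one probe were averaged. A probe was tested if it was well above background in the channel of at least 1 diet on at least 2 arrays and was measured on at least 3 arrays. Of 20868 probes, 8947 were named through the RefSeq accession in the files and a gene table of the GRCm38.p6 assembly, 542 through the symbol in the file's description, and 11379 stayed unnamed. The files name no genome build, so no coordinates are given. For a gene with several probes the one with the highest mean log2 intensity stood for it. Of the 129 symbols with several tested probes, 62 had probes that differed in sign. None of them was among the genes called. Probes of gene families with near-identical members, such as Cyp2b, Cyp2c, Cyp4a, Hsd3b and Mup, can bind more than 1 member.

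The main test was limma's moderated test on log2 ratios with an intercept per gene for the dye effect and the diet coded +1 where CLA was in Cy5 and -1 where it was in Cy3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Values per array are given as log2 CLA over control after the gene's dye effect was taken out, and the residuals on the 2 orientations are tied to the same mean by that step. Fixed gene lists with at least 5 genes tested were compared with the other genes by camera at a preset inter-gene correlation of 0.01, and again by camera with an estimated correlation and by fry, on the 19832 genes measured on all 4 arrays. With an estimated correlation camera takes its degrees of freedom from the few arrays, and at the preset one from the many genes. Its p-values at the preset and the estimated correlation differ for that reason too. Counts of list members are given over all genes and adjusted over the list alone. They cover every tested member, while a list's median and mean diet effect cover only members measured on all 4 arrays.

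The design, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named the 10 largest rises and falls among genes with a symbol, an adjusted p under 0.05 and the same sign on every array, up to 4 called members of each list by p, up to 2 members by p where a list had none called, and every tested gene of a preset list of lipid and glucose genes. The same sign was read as the sign after the dye effect was removed, a reading chosen after the data were seen. All 14 called genes met it, and 8 of them also had the same sign as measured. Genes seen in only 1 diet were to be given as bounds. There were 127 tested genes with no CLA channel and 179 with no control channel well above background on any array, and 10 saturated on all 4 arrays in a diet. No gene chosen by the naming rule was among these bounded or saturated genes. Of the list members, Mup1, Mup4 and Apoa2 were saturated, so no fold is given for them. Some genes that the naming rule chose are not reported here and stay in the list tests and counts.

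Alternatives were the scanner's processed signals, no background subtraction, an offset of 10, median centring in place of loess, Aquantile or equal spread between arrays, no filter or a strict filter on dim probes, outlier flags kept, no dye term, averaging of arrays 1 and 3 with 2 and 4 or of 1 and 4 with 2 and 3, array weights, an intensity trend in the variance prior, the mean of a gene's probes, the series matrix, a minimum change of 1.5-fold, and leaving out each array in turn. Each array had its own slide. Per the file headers, the Feature Extraction software was run on another day for array 2 than for the other 3. A block for that day equals leaving out array 2. It is a day of image analysis, not of RNA extraction or hybridization. Added after the data were seen were offsets of 0 and 16, a threshold of 0.10 and a version in which the size of the dye effect was made equal on the 4 arrays. In it each array's log ratios were regressed on the mean over the arrays and the slope was set to 1. A diet effect that ran parallel to the dye effect across genes would be removed with it.

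The test was checked on simulated arrays of 20083 genes with the measured dye effects and variance for CLA versus control. Each simulation was drawn once, with noise independent between genes. With a dye effect of equal size, 54% of genes changed 1.3-fold, 96% of those changed 1.5-fold and 100% of those changed 2-fold or 3-fold were called. With no gene changed, 0 were called and 1021 had an unadjusted p under 0.05. When the dye effect was given the sizes measured on the 4 arrays and no gene was changed, 34 genes were called and 2111 had an unadjusted p under 0.05. After equalising, 0 were called and 1117 had an unadjusted p under 0.05. A list of 35 genes shifted by 0.2 log2 was found by camera with the preset correlation (adjusted p = 8.46e-31) and not with the estimated one (adjusted p = 0.174). The median standard error of a gene's log2 change was 0.064, and the number of arrays limits this precision. Figures were drawn with Python 3.11.15.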

Results

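The liver response to trans-10, cis-12 CLA, a fatty acid isomer fed to reduce body fat, was measured on day 14 in male mice of a polygenic obese line, against linoleic acid at the same 1% of the diet. There were 4 arrays, 2 with CLA in Cy5 and 2 with CLA in Cy3, each of a pool of 4 or 5 mice per diet. Of the spots outside controls, 80.3% to 95.8% per array and channel were well above background. After filtering, 9135 genes with a symbol and 10948 unnamed probes were tested.

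The comparison of CLA with control asks which liver genes the diet changed. Apoa4, an apolipoprotein of triglyceride-rich particles, rose 1.93-fold (log2 0.95 ± 0.07 SE, n = 4 arrays, limma adjusted p = 0.025). The other named genes that rose were Prm1, a protamine of sperm chromatin (log2 0.66 ± 0.07), Rad51b, a DNA repair gene (0.63 ± 0.06), and Cacna2d2, a calcium channel subunit (0.54 ± 0.06). Hsd3b4, of the 3-beta-hydroxysteroid dehydrogenase family, fell by 0.66 ± 0.07 on the log2 scale, and Cish, a suppressor of cytokine signalling that STAT5 induces, fell by 0.62 ± 0.07. Cyp4f14, which hydroxylates leukotriene B4, fell by 0.53 ± 0.06, and the receptor gene Egfr fell by 0.50 ± 0.06. These 7 had limma adjusted p = 0.043 each. The dye effect of Apoa4 (log2 -1.03), Prm1 (-1.09) and Cacna2d2 (-1.96) was larger in size than the diet effect. As measured, their mean ratio of CLA over control was therefore below 0 where CLA was in Cy5, and the rise came from the arrays with CLA in Cy3.

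In all, 7 genes rose and 7 fell, by 1.41-fold to 1.93-fold. The other 6 were unnamed probes. Among them, and chosen after their values were seen, a probe described in the files as similar to regulator of G-protein signalling 16 rose by 0.73 ± 0.08 (log2), and a probe described as isopentenyl-diphosphate isomerase, an enzyme of cholesterol synthesis, fell by 0.50 ± 0.06. At an unadjusted limma p under 0.05, 1756 genes were higher and 1439 lower, against 2111 in all in simulated arrays with the measured sizes of the dye effect and no changed gene.

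The count of 14 depends on the processing. It was 0 with the scanner's processed signals, without background subtraction, with a smaller background offset, with equal spread between arrays or with no dye term (limma, 291 to 3393 genes at an unadjusted p under 0.05), and with median centring 28 rose and 112 fell. Without array 1, 2, 3 or 4 it was 35, 2, 79 and 73. Of the 14 genes themselves, 5, 0, 13 and 13 were among those called, so no call held without array 2. The dye effect was larger where CLA was in Cy3, with slopes on the mean profile of 0.78 and 0.73 on arrays 1 and 2 and of 1.18 and 1.29 on arrays 3 and 4, and across genes the diet effect had r = -0.52 with the dye effect (genes are not independent replicates). In simulated arrays with dye effects of these sizes and no changed gene, 34 genes were called, more than the 14 observed. That was 1 draw, and its r of diet with dye effect was -0.60, further from 0 than in the data. The 34 are therefore only a rough guide. Made equal in size on all arrays, a version chosen after seeing the data, the dye effect left 0 genes at an adjusted p under 0.05 with limma (1890 at an unadjusted p under 0.05, 942 of them higher). There were 15 at an adjusted p under 0.10, of which 9 were among the 14. In that version Cish stood at -0.69 ± 0.07, Apoa4 at 0.70 ± 0.08, Hsd3b4 at -0.58 ± 0.07, Rad51b at 0.55 ± 0.06, Cyp4f14 at -0.50 ± 0.06 and Egfr at -0.46 ± 0.06, each with an adjusted p of 0.087. Prm1 stood at 0.40 ± 0.06 (adjusted p = 0.152) and Cacna2d2 at 0.07 ± 0.06 (adjusted p = 0.665).

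**Figure D1:**
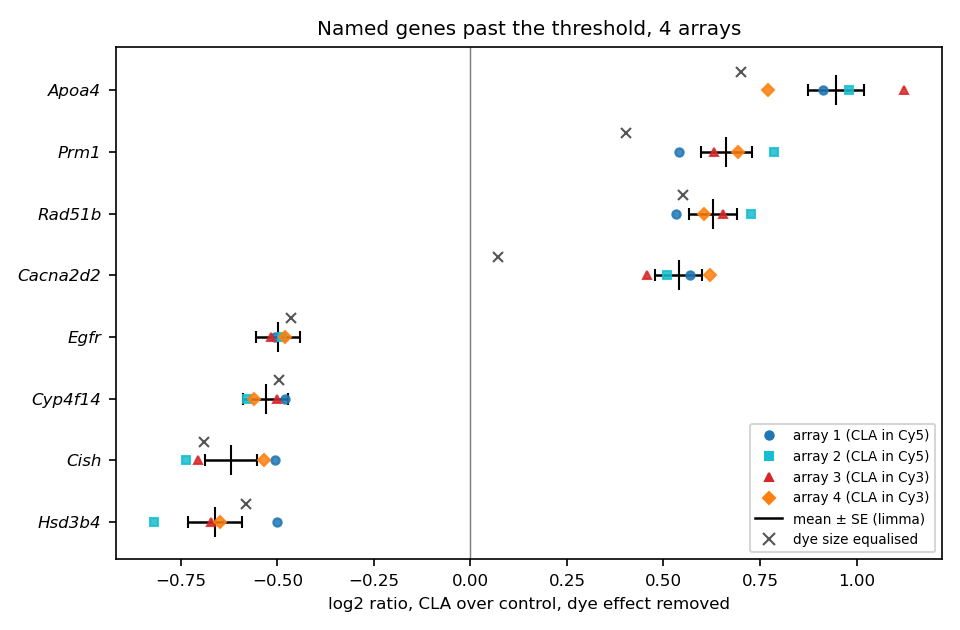
Log2 ratio of CLA over control for the 8 named genes past the threshold, 1 point per array after the gene's dye effect was removed, with the limma mean and its SE as bars and the value with the dye size equalised as a cross. Removing the dye effect gives both dye orientations the same mean for a gene. Cish moved from -0.62 to -0.69 and Cacna2d2 from 0.54 to 0.07 when the dye size was equalised.

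**Figure D2:**
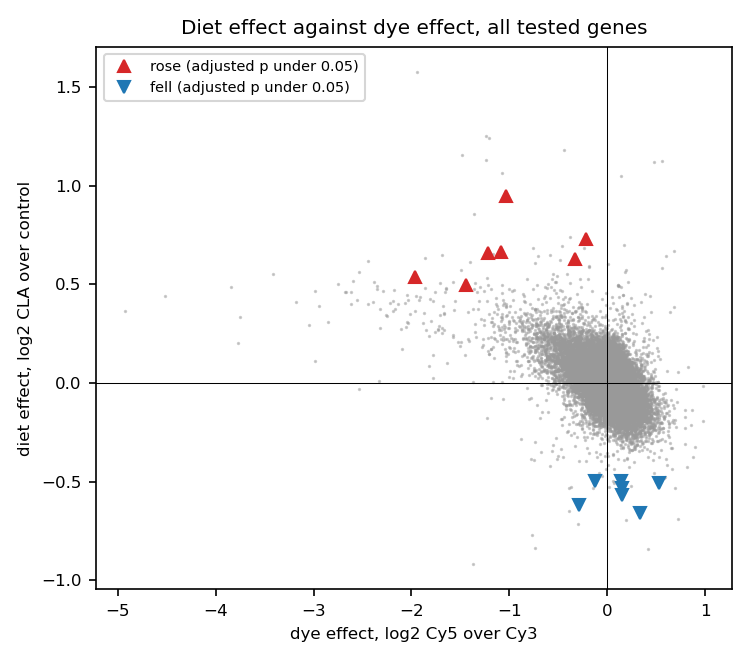
Diet effect (log2 CLA over control) against dye effect (log2 Cy5 over Cy3) of every tested gene, grey points, with the 7 genes that rose as red triangles and the 7 that fell as blue triangles. The cloud slopes down (r = -0.52), and all 7 genes that rose had a dye effect below 0.

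Genes of peroxisomal and microsomal fatty acid oxidation were higher with CLA as a group. Of 19 tested, 18 lay above 0 (median log2 0.21), none was called over all genes, and 10 rose when adjusted over the list alone. Abcd3, a peroxisomal importer of fatty acids, stood at 0.50 ± 0.06 (adjusted p over all genes 0.051), and Ech1, an enoyl-CoA isomerase, at 0.36 ± 0.06 (adjusted p = 0.075). Abcd3 stood at 0.20 ± 0.06 (adjusted p = 0.505) with the dye size equalised, where 10 genes rose over the list alone, 9 of them among the 10 before. Cyp4a14, a fatty acid omega-hydroxylase, had the largest change of the list, 1.12 ± 0.35 (adjusted p = 0.204), which rested largely on array 2 (3.01 as measured there, and 0.22 to 0.91 on the others). Without array 2 it was 0.46, and without array 1 1.79 (adjusted p = 0.016). The list shifted up in camera (adjusted p = 6.17e-09), and its adjusted p was 0.538 with an estimated correlation.

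Mitochondrial fatty acid oxidation moved the same way. There 10 of 12 tested genes lay above 0 (median log2 0.16), and 5 rose when adjusted over the list alone, among them Acsl1, an acyl-CoA synthetase (0.48 ± 0.08), and Hadh, of the beta-oxidation spiral (0.31 ± 0.06), while Ucp2 stood at -0.01 ± 0.07. Camera gave an adjusted p of 0.00040, and of 0.538 with an estimated correlation. With median centring the shift was no longer past the threshold (adjusted p = 0.386). Of the 23 genes on this list, Cpt1a, Acadl, Acadvl, Hadha and Hadhb were among those with no tested probe under their symbol. Of ketone body genes 4 were tested, too few for a list test. Fgf21, a liver hormone of fasting, stood at 0.22 ± 0.11.

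Lower with CLA as a group were the genes of cholesterol synthesis and uptake, of which 11 of 16 lay below 0 (median log2 -0.09). Unnamed probes are not counted. Among them, and picked after their values were seen, were isopentenyl-diphosphate isomerase and homologs of insulin-induced protein 1 and delta(14)-sterol reductase. These lay below 0, and other unnamed probes of the list were not looked for. Over the list alone 6 fell and 2 rose. As measured on arrays 1 to 4, dye effect not removed, the list's median log2 ratio was -0.42, -0.54, 0.33 and 0.24. Msmo1, a sterol C4 demethylase, stood at -0.49 ± 0.08 (adjusted p = 0.070). Camera gave an adjusted p of 0.020, and 0.538 with an estimated correlation. With the dye size equalised 12 of 16 lay below 0 (median log2 -0.23) and 9 fell and 1 rose over the list alone (camera adjusted p = 5.99e-06, and 0.472 with an estimated correlation). Without array 4 the camera adjusted p was 0.082, and with the processed signals 0.121.

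The bile acid list was also lower, with 12 of 18 genes below 0 (median log2 -0.08) and 5 falling and 3 rising over the list alone. Its leading members, Cyp7b1 (-0.71 ± 0.10, adjusted p = 0.059) and Cyp27a1 (-0.51 ± 0.07, adjusted p = 0.057), belong to the alternative pathway of bile acid synthesis, and Cyp7a1, the rate-limiting enzyme of the classical pathway, stood at -0.02 ± 0.06. Of the amino acid and urea list, 14 of 19 genes lay below 0 (median log2 -0.04), and 7 fell and 1 rose over the list alone. Oat, ornithine aminotransferase, stood at -0.53 ± 0.08 (adjusted p = 0.065). Both lists had a camera adjusted p of 0.020, and with an estimated correlation of 0.538 and 0.642. Leaving out array 3 ended both calls (adjusted p = 0.076 for bile acids and 0.404 for amino acids), as did leaving out array 2 (adjusted p = 0.057 and 0.052). Over the list alone, 4 bile acid genes fell and 1 rose with the dye size equalised, and 4 amino acid genes fell and 0 rose (median log2 of the amino acid list -0.14).

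The list of major urinary proteins and male-biased liver genes was lower, with 5 of 8 tested genes below 0 (median log2 -0.41). Egfr fell over all genes, and over the list alone 4 fell and 2 others passed. Cyp7b1, which this list shares, stood at -0.71 ± 0.10. The 2 others, named here after their values were seen, were Mup1 and Mup4, which lay above 0 and whose spots were saturated. Camera gave an adjusted p of 0.014, and 0.538 with an estimated correlation. It was 0.078 with the scanner's processed signals. Of 12 female-biased genes tested, 8 lay above 0 (median log2 0.11), and 3 rose and 1 fell over the list alone. Cyp2b13, a female-biased cytochrome P450, stood at 1.05 ± 0.16 and Cyp2c40, another, at -0.52 ± 0.08 (adjusted p = 0.065 both). This list did not pass the threshold in camera (adjusted p = 0.116), and did so with the dye size equalised (adjusted p = 0.0077, and 0.472 with an estimated correlation).

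**Figure D3:**
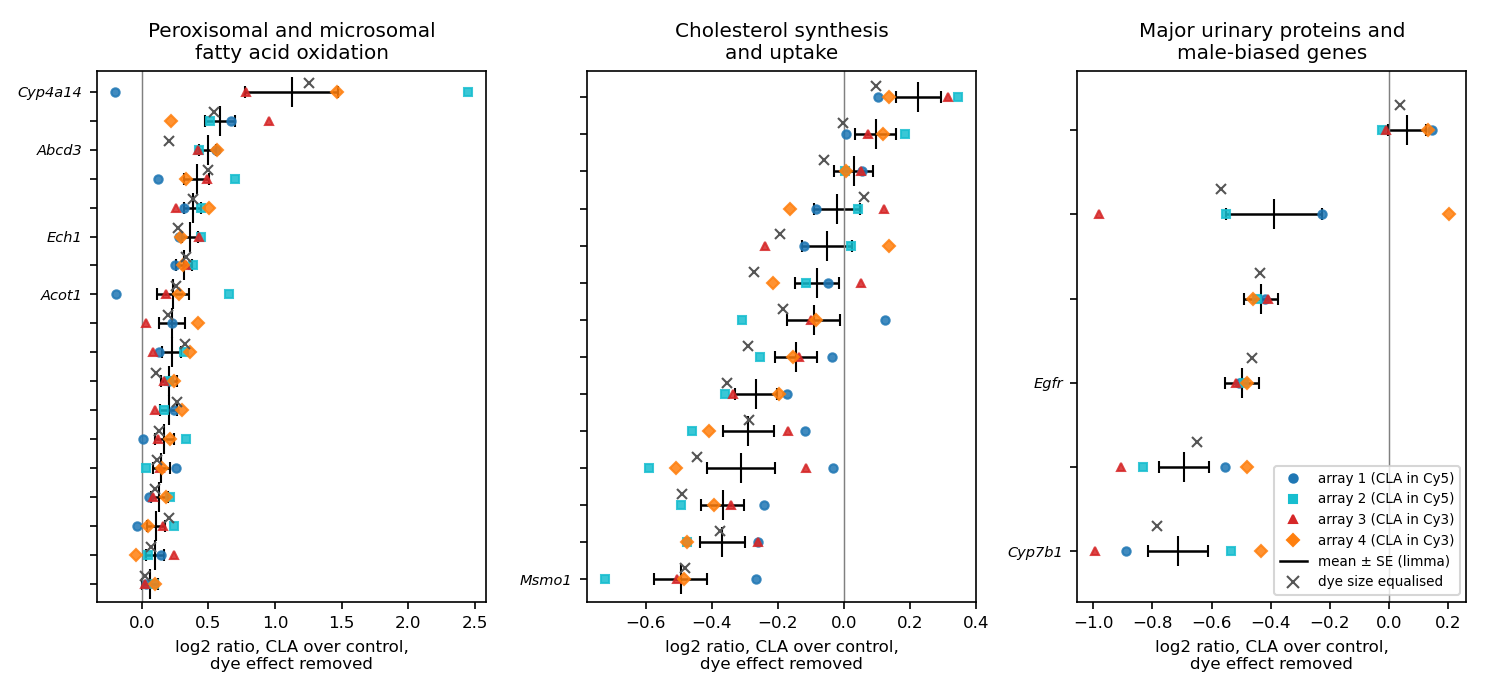
Log2 ratio of CLA over control for tested members of 3 gene lists, without saturated genes and genes not reported here, 1 gene per line with labels for those named in the text, 1 point per array after the gene's dye effect was removed, with the limma mean and SE as bars and the value with the dye size equalised as a cross. Most means of the peroxisomal and microsomal oxidation genes lie above 0, and most of those of the cholesterol genes and of the male-biased genes drawn lie below 0.

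The lipoprotein and plasma lipid transport list was higher, with 17 of 26 genes above 0 (median log2 0.15), 10 rising and 2 falling over the list alone, but its mean was below 0 with median centring (-0.06). Apoa4 rose over all genes, and Fabp1, the liver fatty acid binding protein (0.33 ± 0.10), and Cd36, a fatty acid transporter (0.57 ± 0.18), rose over the list alone. Cd36 was 0.25 without array 2, and Fabp1 0.17 without array 3. Lpl stood at -0.09 ± 0.08. The list's median log2 ratio as measured, dye effect not removed, was -0.10, -0.08, 0.16 and 0.12 on arrays 1 to 4. Camera gave an adjusted p of 0.019, and 0.538 with an estimated correlation, and fry, which asks whether the genes move one way on balance, gave 0.041. Fry gave 0.107 with the dye size equalised, where the median was 0.03 and 8 rose and 2 fell over the list alone. Without array 1 the camera adjusted p was 0.102.

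The proteasome, tricarboxylic acid cycle, and endoplasmic reticulum stress and heat shock lists were higher in camera, and all 3 had means below 0 with median centring (-0.09, -0.10 and -0.08). As measured on arrays 1 to 4, dye effect not removed, the proteasome list had median log2 ratios of -0.0047, -0.11, 0.22 and 0.17. Those of the tricarboxylic acid cycle list were -0.07, 0.06, 0.28 and 0.34, and those of the stress list -0.33, -0.09, 0.48 and 0.28. Of 25 proteasome genes 23 lay above 0 (median log2 0.06, adjusted p = 0.0059), and 1, Psmc5, a subunit of the regulatory cap (0.29 ± 0.06), rose over the list alone, with Psmc6 of the same cap at -0.23 ± 0.06. Of 15 tricarboxylic acid cycle genes 12 lay above 0 (median log2 0.11, adjusted p = 0.023), and 3 rose over the list alone, among them Idh2 (0.29 ± 0.07) and Pdha1 (0.24 ± 0.06). Of 21 endoplasmic reticulum stress and heat shock genes 17 lay above 0 (median log2 0.11, adjusted p = 0.019). Over that list alone 1 rose, Herpud1, of protein degradation at the reticulum (0.44 ± 0.06, adjusted p over all genes 0.052), and 2 fell, Xbp1, a transcription factor of the stress response (-0.29 ± 0.06), and Calr, calreticulin, named after its values were seen (-0.25 ± 0.07). With an estimated correlation the adjusted p was 0.538, 0.538 and 0.642. Equalising the dye size ended the calls for proteasome (adjusted p = 0.135) and stress genes (adjusted p = 0.372, median log2 0.03), leaving out array 2 or array 3 ended that of the stress genes (adjusted p = 0.239 and 0.061), and leaving out array 1 or array 4 ended that of the tricarboxylic acid cycle (adjusted p = 0.105 and 0.095). No member of the proteasome or tricarboxylic acid cycle lists passed over the list alone with the dye size equalised, where Psmc5 stood at 0.07 ± 0.06, Psmc6 at -0.15 ± 0.06, Idh2 at 0.12 ± 0.06 and Pdha1 at 0.10 ± 0.06.

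The tested genes of fatty acid synthesis and of triglyceride storage did not shift as lists. Of 13 fatty acid synthesis and desaturation genes tested 7 lay above 0 (camera adjusted p = 0.885). Over the 12 of them measured on all 4 arrays the median was -0.0036 and the mean 0.05. Of the 20 genes on this list, Fasn, Acaca, Acacb, Acly, Srebf1, Fads1 and Acsl5 had no tested probe under their symbol. The list test says nothing on those genes. Over that list alone 3 rose, namely Fads2, the delta-6 desaturase (0.34 ± 0.06), Pklr, liver pyruvate kinase (0.38 ± 0.08), and Scd1, stearoyl-CoA desaturase (0.43 ± 0.12). None did with the dye size equalised, where Fads2 stood at 0.16 ± 0.06, Pklr at 0.25 ± 0.08 and Scd1 at 0.29 ± 0.12. Without array 2 Scd1 was 0.23. Me1, malic enzyme, stood at 0.37 ± 0.13 and Elovl6, a fatty acid elongase, at 0.16 ± 0.17. Of 20 triglyceride and lipid droplet genes 14 lay above 0 (median log2 0.13, adjusted p = 0.103) and none passed over the list alone. Agpat3 stood at 0.26 ± 0.06, Plin2, a lipid droplet coat protein, at 0.33 ± 0.11, Mogat1 at 0.29 ± 0.11, Cidea at 0.29 ± 0.11 and Cideb at -0.28 ± 0.09. Agpat3 stood at 0.17 ± 0.06, Cidea at 0.08 ± 0.10 and Cideb at -0.15 ± 0.08 once the dye size was equalised. The list's median was then 0.03. Plin2 was 0.17 and Mogat1 0.12 without array 2.

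For glycolysis and gluconeogenesis 15 of 21 genes lay above 0 (adjusted p = 0.244). G6pc, the last enzyme of glucose release, stood at -0.53 ± 0.07 (adjusted p over all genes 0.052), and fell over the list alone, where 5 rose and, with the dye size equalised, 0 did. Pck1, of gluconeogenesis, stood at 0.04 ± 0.10, and at -0.24 with median centring. Of 18 insulin and growth factor signalling genes 11 lay below 0 (adjusted p = 0.589), with Igfals at -0.23 ± 0.06, Ghr, the growth hormone receptor, at -0.25 ± 0.08, and Igfbp1 at -0.21 ± 0.29. Once the dye size was equalised Ghr stood at -0.14 ± 0.08, and Igfals fell over the list alone (-0.29 ± 0.06). Of the nuclear receptors of the preset key genes, Ppara stood at 0.10 ± 0.07 and Pparg at 0.09 ± 0.07, both below 0 with median centring. Of the 22 preset key genes tested, 1 rose over all genes, and 6 rose and 1 fell over the list alone. The preset list holds 30 genes, and probes that stayed unnamed are not counted.

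Of 26 xenobiotic phase I genes 16 lay above 0 (adjusted p = 0.166), with 8 rising and 3 falling over the list alone, and 5 and 2 with the dye size equalised. Of 21 glutathione, phase II and antioxidant genes 12 lay above 0 (adjusted p = 0.916), and Ephx1, an epoxide hydrolase (0.54 ± 0.09), and Gclm, of glutathione synthesis (0.23 ± 0.06), rose over the list alone, where 1 fell, Gsta3, named after its values were seen (-0.22 ± 0.06). Of 21 acute phase genes 12 lay above 0 (adjusted p = 0.966), and over the list alone 2 rose, among them Saa4 (0.30 ± 0.07), and 1 fell, Hamp, hepcidin (-0.32 ± 0.08). Of 40 oxidative phosphorylation genes 27 lay above 0 (adjusted p = 0.078), with Uqcrc1 at 0.28 ± 0.06 and Cyc1 at 0.26 ± 0.06. Of 35 ribosomal protein genes 23 lay below 0 (adjusted p = 0.204), with Rpl23 and Rps25 at -0.17 ± 0.06 each. The cell cycle (13 of 23 below 0, adjusted p = 0.592), interferon (11 of 20 below 0, adjusted p = 0.166) and circadian clock lists (8 of 13 below 0, adjusted p = 0.592) did not shift. Their leading members were Ccnb1 at -0.21 ± 0.06, Ifit1 at -0.29 ± 0.07 and Npas2, a clock transcription factor, at 0.32 ± 0.07, which alone of these lists' members rose over its list alone. With the dye size equalised Npas2 stood at 0.02 ± 0.08, Saa4 at 0.13 ± 0.06, Hamp at -0.11 ± 0.08, Uqcrc1 at 0.14 ± 0.06, Rps25 at -0.08 ± 0.06 and Ccnb1 at -0.14 ± 0.06. Without array 2 Hamp was -0.22. No acute phase or clock gene then passed over its list alone, and of the glutathione list 1 did, Ephx1 (0.42 ± 0.08), with Gclm at 0.16 ± 0.06 and Gsta3 at -0.14 ± 0.06. With it equalised, 3 lists of this group passed the camera threshold: ribosomal proteins (30 of 35 below 0, adjusted p = 0.0018), oxidative phosphorylation (31 of 40 above 0, adjusted p = 0.0031) and acute phase proteins (13 of 21 below 0, adjusted p = 0.031). With an estimated correlation the adjusted p of these 3 was 0.593, 0.472 and 0.644.

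Markers of other cell types were set beside these lists. All 10 tested genes of the exocrine pancreas lay above 0 (median log2 0.33, camera adjusted p = 0.0040), none was called, and none passed over the list alone. With an estimated correlation the adjusted p was 0.642. The shift came from array 4, where the list's median log2 ratio was 1.18 as measured, against 0.05, 0.07 and -0.02 on arrays 1, 2 and 3. Without array 4 the adjusted p was 0.812. Prss2, a trypsinogen, was 6.04-fold higher for CLA on array 4, chosen after its values were seen, and Ctrb1, chymotrypsinogen, was 2.57-fold higher there. In the fit over all arrays Ctrb1 stood at 0.45 ± 0.16 and Pnlip, pancreatic lipase, at 0.33 ± 0.12. As measured on arrays 1 to 4, Ctrb1 was at 0.11, 0.16, 0.17 and 1.36. Pnlip was at 0.03, 0.58, 0.03 and 0.69, so it was higher on array 2 as well.

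**Figure D4:**
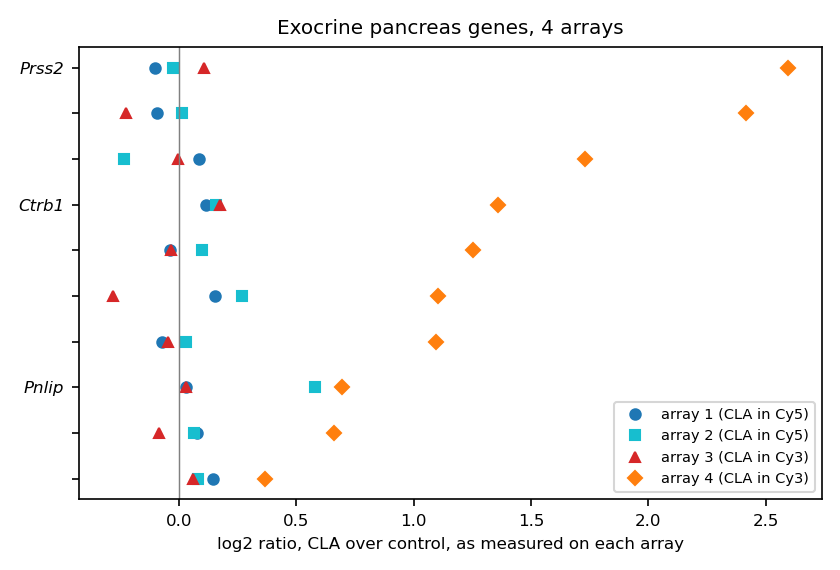
Log2 ratio of CLA over control as measured on each array, dye effect not removed, for the 10 tested exocrine pancreas genes, with labels for those named in the text. On array 4 all 10 lie above 0, up to 2.60 for Prss2.

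The other cell type lists did not pass the threshold. The camera adjusted p was 0.120 for hepatocytes (7 of 9 above 0, led by Tdo2 at 0.41 ± 0.11 and Trf at 0.22 ± 0.08, the latter near 0 at -0.0070 with the dye size equalised), 0.893 for Kupffer cells and macrophages (9 of 14 above 0, Marco at 0.13 ± 0.07) and 0.140 for lymphocytes and neutrophils (12 of 17 above 0, Cd3g at 0.25 ± 0.08). It was 0.537 for stellate cells and matrix (9 of 15 above 0, Acta2 at 0.39 ± 0.08), 0.439 for endothelial cells (8 of 13 below 0, Ehd3 at -0.19 ± 0.08) and 0.204 for cholangiocytes (9 of 11 above 0, Cldn7 at 0.28 ± 0.07). It was 0.439 for erythroid cells (5 of 9 below 0) and 0.660 for skeletal muscle (5 of 10 above 0, Tnnc1 at 0.24 ± 0.07). For adipocytes it was 0.096 (10 of 13 above 0), with Retn at 0.27 ± 0.07 and Sncg at 0.36 ± 0.06, the latter at -0.09 with the dye size equalised. Over its list alone 1 member rose for hepatocytes (Tdo2), stellate cells (Acta2) and cholangiocytes (Cldn7), and 3 rose for adipocytes. None of these 4 lists had such a member with the dye size equalised, where Acta2 stood at 0.12 ± 0.07, Retn at 0.16 ± 0.06, Marco at 0.04 ± 0.06 and Ehd3 at -0.02 ± 0.08. The lymphocyte and neutrophil list then passed in camera (adjusted p = 0.032, and 0.472 with an estimated correlation). Without array 4 Tdo2 was 0.27.

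Of the 33 lists tested, 11 passed in camera at the preset correlation, none with an estimated correlation and 1 in fry, which with the dye size equalised passed no list (lowest adjusted p 0.076). Camera with an estimated correlation also missed a simulated list shifted by 0.2 log2 (adjusted p = 0.174), so its lack of calls cannot show that no list moved. For the proteasome, tricarboxylic acid cycle, lipoprotein and male-biased lists the estimate was -0.020, -0.018, -0.039 and -0.093, below the preset 0.01. A higher correlation between genes therefore did not end these calls. With an estimated correlation camera takes its degrees of freedom from the few arrays, and at the preset one from the many genes. For every list this by itself raises the p-value with an estimated correlation. With the scanner's processed signals 4 passed in camera, and with an offset of 10 there were 5. The peroxisomal and microsomal oxidation list passed in each of the 21 alternatives left without Aquantile, which changed no log ratio, and the series matrix, which repeated the processed signals, and the mitochondrial list in 20 of them. Of the 22 lists that did not pass, 13 passed in at least 1 alternative. With 1 array left out, none passed with an estimated correlation (lowest adjusted p 0.651). So few arrays leave that test hardly able to pass, and its result says nothing against the calls at the preset correlation. Some lists passed at the preset correlation when 1 array was left out. Without array 1 these were acute phase proteins, higher (adjusted p = 0.030), and without array 2 acute phase proteins, lower (0.0018), triglyceride genes (0.020), hepatocyte markers (0.018), glycolysis (0.025) and oxidative phosphorylation (0.033). Without array 3 they were xenobiotic genes, hepatocyte markers and Kupffer cell markers, higher (0.012 each), female-biased genes (0.012) and adipocyte markers (0.044). Without array 4 they were Kupffer cell markers, lower (0.013), triglyceride genes (0.025), oxidative phosphorylation (0.030) and ribosomal proteins (0.032).

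In the authors' deposited table of 775 significant probes, 364 had a ratio above 1 and 411 below. The table was chosen on these arrays and is not independent evidence of direction. Of its probes 765 were tested here, 741 of them (96.9%) with the same sign, and 334 with the same sign and an unadjusted limma p under 0.05. Of the 14 genes called here 7 were in the table. Across those probes the authors' log2 ratio had r = 0.83 with the diet effect fitted here, and r = -0.31, 0.45, 0.82 and 0.81 with arrays 1 to 4 alone before the dye effect was removed.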

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

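All tests in this part were chosen after the results were seen. An array was picked out where its CLA over control log2 ratio, as measured, or a quality measure stood far from the other 3. Of 136 results looked at, 7 showed this, and a rate of 1 in 20 would give about 7. That rate holds for independent results without a dye effect. These results overlap and the ratios keep the dye effect, so the number expected by chance is not known.

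Exocrine pancreas genes stood apart on array 4 with a median log2 ratio of 1.18, and Ctrb1 with 1.36. The highest median on the other arrays was 0.0735, which argues against a diet effect shared by the arrays. A candidate explanation is pancreas tissue taken with liver into that pool. All 10 tested genes were at least 1.2-fold higher for CLA on that array, but this largely restates the median and leaves that explanation open, and the labels do not say whether another array held the same pool. That liver cells of those mice expressed these genes stays open and untested.

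The triglyceride synthesis and lipid droplet list stood apart on array 3 (median log2 ratio 0.30), and the glutathione and phase II list on array 4 (0.22). Tef stood apart on array 1 (0.0535). Array 2 had the highest median green intensity (468.8) and the most spots marked as outliers by the scanner software (148).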

How the results depend on the processing

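The offsets of 0 and 16, the threshold of 0.10 and the equalised dye size were chosen after the data were seen, the other alternatives before. The numbers of genes that changed, rose and fell (14, 7 and 7) were 0, 0 and 0 with limma on processed signals or series matrix values (2739 at an unadjusted p under 0.05), without background subtraction (3393), with normexp offsets of 10 (2774), 0 (2525) or 16 (2924), with equal spread between arrays (1584), with no dye term (291) and with the dye size equalised (1890). They were 140, 28 and 112 with median centring, 57, 38 and 19 for probes well above background in both channels on all arrays, 1189, 774 and 415 with arrays 1 and 3 and arrays 2 and 4 averaged, 220, 163 and 57 with arrays 1 and 4 and arrays 2 and 3 averaged, and 47, 35 and 12 with an intensity trend. At a change of at least 1.5-fold they were 7, 5 and 2, at an adjusted p under 0.10 177, 126 and 51, and with that threshold and the dye size equalised 15, 4 and 11. Leaving out each array in turn gave 2 to 79 changed, 2 to 62 rising and 0 to 20 falling, and 10 to 13 lists. The other alternatives gave 13 or 14 changed. All 14 genes had the same sign in every alternative, and each was called in 9 to 13 of 23. None of the 14 was called without array 2. The number of lists that shifted (11) was 4 with processed signals or series matrix values, 5 with offsets of 10, 0 or 16, 7 with no dye term, 0 with an estimated correlation and 1 with fry. Over the 11 lists called and the alternatives, 197 values kept direction and side of the threshold, 52 lost the call and 4 changed sign, all with median centring: lipoproteins (-0.060), stress and heat shock (-0.085), tricarboxylic acid cycle (-0.095) and proteasome (-0.089). The 22 lists not called gained 38 calls in 506 values. Aquantile changed no value and the series matrix repeated the processed signals, so 21 of the 23 alternatives are distinct, and counts over alternatives include both. For named genes, with the called unnamed probes counted in, 1724 kept both, 155 lost the call, 95 gained one and 20 changed sign, none of them of a called gene. Those were Trf (-0.070), Mylpf (0.026), Ppara (-0.11), Pparg (-0.073), Elovl6 (-0.037) and Pck1 (-0.24) with median centring, Trf (-0.0070), Sncg (-0.091) and Ucp2 (0.043) with the dye size equalised, and Ucp2 (0.011) with equal spread. Over the arrays left out in turn the range was -0.27 to 0.0028 for Mylpf, -0.19 to 0.0055 for Lpl, -0.072 to 0.40 for Elovl6, -0.73 to 0.30 for Igfbp1, -0.14 to 0.21 for Pck1, -0.067 to 0.024 for Cyp7a1 and -0.087 to 0.071 for Ucp2. Averaging arrays or leaving one out changes the number of samples, and for the other alternatives the cause was not tested. The pairs of arrays that were averaged are not given by the labels. Signal over background limits dim genes, with 80.3% of red and 93.2% of green spots well above background on array 1.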

Other observations

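All tests in this part were chosen after the results were seen. Of 7 genes of fatty acid handling looked at after their values were seen, 5 had their highest ratio on array 2 and the other 2 on array 1 or array 3. The log2 ratio of CLA over control as measured on arrays 1 to 4 was 0.36, 3.01, 0.22 and 0.91 for Cyp4a14 and 0.11, 1.42, 0.16 and 0.61 for Cd36. For Acot1, a peroxisome proliferator target like both, it was -0.08, 0.77, 0.07 and 0.17. Rpl28 had the lowest ratio of the tested genes on that array, at -4.0, against -0.58 on array 1 with the same dyes. None of these had an adjusted p under 0.05 with limma.

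Made 1 size on all arrays, the dye effect left the 14 genes called at different shares of their log2 change: of the 7 that rose, 5 moved towards 0 by more than 2 standard errors (median share left 60.8%), and of the 7 that fell, 1 did (93.5%). Simulated arrays with the measured dye sizes and no changed gene gave 34 calls, so unequal dye size may account for part of the rises, Cacna2d2 most of all (0.54 ± 0.06 before and 0.07 ± 0.06 after). As the whole cause of the falls it is argued against, since 6 of the 7 kept their size within 2 standard errors. Their calls ended as well: for 2 of them, Cish among these (-0.62 ± 0.07 before and -0.69 ± 0.07 after), p fell while the adjusted p rose, so the adjustment over all genes ended the call, and for the other 5 p itself rose too. The 3 splits of the 4 arrays into 2 and 2 are too few for a share under 0.05: 1 split, the real one, gave as many genes (14), and the highest other gave 2.

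Cish and the male-biased list were lower together, which suggests the hypothesis of weaker growth hormone and STAT5 signalling, although Mup1 and Mup4 of that list lay above 0, at saturated spots. Unequal dye size is argued against, since the list had an adjusted p of 0.0017 once it was equalised (0.472 with an estimated correlation, and 0.000018 to 0.078 over the alternatives at the preset correlation), and so is a single array, since the highest adjusted p without each array in turn was 0.0318. On a further list, written after many values had been seen and leaving out candidates such as Ghr, 6 of 7 genes induced by growth hormone or higher in males lay below 0 with the dye size equalised (exact two-sided sign test p = 0.125), among them Socs2 (-0.20 ± 0.07) and Igf1 (-0.18 ± 0.06). Without equalising, Socs2 stood at -0.14 and Igf1 at -0.10. Of 6 further female-biased genes 2 lay above 0, where the hypothesis predicts a rise (exact two-sided sign test p = 0.688). These few genes leave the hypothesis open, and lower food intake, which the labels do not report, was not tested.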
